A study of Mus musculus with 24 samples.

How the data were processed

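The data are RNA-seq profiles of whole lung from young male C57BL6/j mice kept for 2 days in normoxia or hypoxia while receiving vehicle or ABT-263 at 50 mg/kg/day. ABT-263, also called navitoclax, is an inhibitor of BCL-2, BCL-XL and BCL-W that is used as a senolytic, a drug given to remove senescent cells. The libraries fall into 4 groups of 6, and normoxia with vehicle is the control. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a stranded mRNA kit and sequenced on a NextSeq. The labels number no animals, so the replicate numbers used here only name libraries, and the p-values measure only the spread between these libraries, which may be partly technical if 1 animal gave several.

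The authors deposited a table of expected counts per gene, 1 column per library, as RSEM gives them. Per the submitters' processing notes, Trimmomatic, STAR and RSEM were used with the GRCm38 build. Their versions, the annotation release, the strand setting of the counting and any filters are not given in the sources used here. All columns of the table matched a library, and 0 columns were left unmapped. The table held 54532 genes, of which 33582 had a count in some library. Of its values, 91.8% were whole numbers, and the fractions are at genes whose reads RSEM divided between genes. RSEM shares reads between near-identical copies by estimation, so the haemoglobin genes (Hba-a1 with Hba-a2, Hbb-bs with Hbb-bt), Chil3 with Chil4, and Orm1, Orm2 and Orm3 are uncertain as single genes. Genes that overlap another gene are uncertain too, on the opposite strand because the counting may have ignored strand. Among the 72 genes named by rule, 7 overlapped a gene on the same strand and 21 a gene on the opposite strand.

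Total expected counts ran from 12643500 to 17295200 per library. CPM are the counts scaled to a library of 1e+06. At these totals counting error weighs most at low CPM, but it was not small beside the spread between libraries for every gene above a few CPM. For Mfsd2b in normoxia with vehicle (mean ± SD 6.52 ± 0.669 CPM, n = 6) counting error and spread were about equal. Where a group held 0 counts of a gene, the fold is given against a floor of 3 counts over the group. Where it held 1 to 3, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries of a group agreed within sampling noise: the lowest chi-square per degree of freedom was 7.11, and the correlations of log2 CPM within groups lay between 0.966 and 0.989. Each library was counted as 1 replicate, although these values cannot show whether libraries come from separate animals.

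Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr with its minimum count of 10, which left 16935 genes, and library sizes were scaled by TMM. The quasi-likelihood F test was fitted robustly with 1 mean per group to all 24 libraries, which gave 20 residual degrees of freedom. The comparisons were hypoxia against normoxia under vehicle, ABT-263 against vehicle in normoxia, the same in hypoxia, hypoxia against normoxia under ABT-263, and the interaction of hypoxia with ABT-263. A gene counts as changed at a Benjamini-Hochberg adjusted p under 0.05. Levels are TMM-scaled CPM, given as mean ± SD over the 6 libraries of a group. Haemoglobin and mitochondrial shares, total counts and numbers of detected genes were compared by exact two-sided permutation of the 12 libraries, whose smallest possible p is 0.00216, with Benjamini-Hochberg adjustment over 16 tests.

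Gene lists for lung and blood cell types and for pathways, 45 in all, were written before the data were examined, as were the comparisons, the tests and the rule for named genes. Each list was tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Every list call was repeated with the correlation estimated from the data and with fry. Except for the interaction, it was also repeated with an exact permutation of the mean log2 CPM of the list. Single members were counted after adjustment over all genes and adjusted over the list alone.

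The rule for named genes took, in each of the 3 main comparisons, the 6 genes that rose and the 6 that fell with the largest fold change among those past the threshold with a mean of 1 CPM or more in a group, leaving out gene models, pseudogenes and receptor segments. It added the 3 members with the smallest p of the 5 lists with the smallest camera p, and in every comparison Cdkn2a, Cdkn1a, Bcl2, Bcl2l1, Bcl2l2, Pf4 and Vegfa. For hypoxia under ABT-263 and the interaction the numbers were 3 and 3 genes and 2 members of 2 lists. Where no gene passed, the 3 with the smallest p are named as not passing. Other genes named are members of the lists or were chosen after their values were seen, as stated where they appear.

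The alternatives were DESeq2 size factors in edgeR, DESeq2 1.42.0, limma-voom on the unrounded values, no filter and a stricter filter of a mean of 1 CPM, only the groups compared, haemoglobin and mitochondrial genes removed, and each of the 24 libraries left out in turn. Chosen after seeing the data were a fit without 3 libraries that stood apart on the leading components (normoxia vehicle 2, normoxia ABT-263 5 and hypoxia ABT-263 1), a fit with the first residual component as covariate, and the permutation of list scores. The tests were tried on simulated counts with 200 changed genes drawn from the means and library sizes of the real libraries. The simulated genes varied independently, whereas real genes vary together within groups, so the shares called may be too high for the real libraries. For ABT-263 in normoxia, 52.2% of the 67 simulated 1.5-fold changes, 85.1% of the 67 2-fold changes and 97.0% of the 66 4-fold changes were called. For ABT-263 in hypoxia the shares were 55.2%, 88.1% and 95.5%. For the interaction they were 20.9%, 52.2% and 89.4%.

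Gene identifiers and symbols are those of the table. Positions are from the GENCODE M21 annotation of GRCm38, in which 54409 of the 54532 identifiers (99.8%) and all 72 named genes were found. They are 1-based. All tests are two-sided. Raw reads, isoforms, and physiological measurements of the animals were not analysed here.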

Results

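Gene expression was measured by RNA-seq in 24 whole-lung libraries from young male C57BL6/j mice. The 4 groups, each of 6 libraries, combined 2 days of normoxia or hypoxia with vehicle or the BCL-2 family inhibitor ABT-263. Total expected counts did not separate the groups: they averaged 15496800 ± 1515300 (SD, n = 6) in normoxia with vehicle and 15171500 ± 1182040 (SD, n = 6) in hypoxia with vehicle (exact permutation p = 0.677). Haemoglobin transcripts, which come from red cells and their precursors, took 0.385% ± 0.0800 of the counts in normoxia with vehicle and 1.47% ± 0.360 in hypoxia with vehicle (SD, n = 6 each). That difference was larger than the spread between libraries (exact permutation p = 0.00216, adjusted over 16 tests 0.0173). Under ABT-263 the share was 0.600% ± 0.214 in normoxia and 1.74% ± 0.589 in hypoxia, and the drug's difference passed at neither oxygen level (adjusted exact permutation p = 0.277 and 0.784). Mitochondrially encoded transcripts took 3.71% to 4.88% of the counts in the group means, and no comparison of them passed. On the first principal component of log2 CPM, which held 38.2% of the variance, all 12 hypoxia libraries lay apart from all 12 normoxia libraries.

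**Figure D1:**
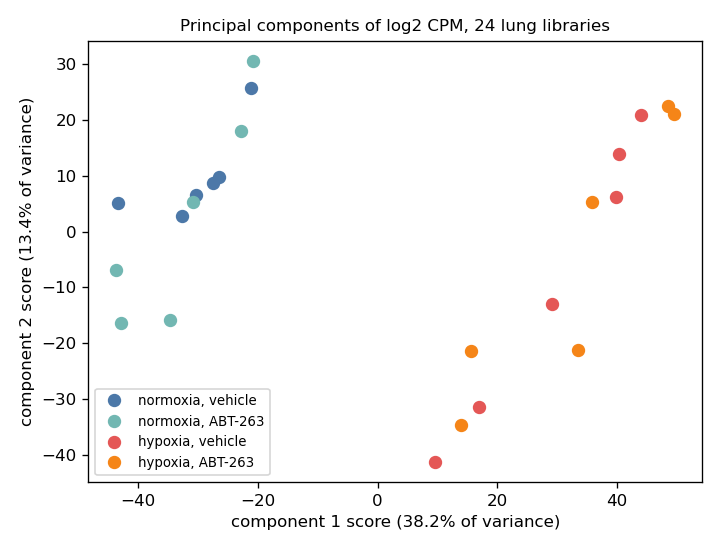
Scores of the 24 libraries on the first (38.2% of variance) and second (13.4%) principal components of log2 CPM; each point is a library, coloured by group. The hypoxia libraries score 9.66 or higher on component 1 and the normoxia libraries -20.8 or lower, while vehicle and ABT-263 points are mixed at each oxygen level.

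The first comparison asked how the lung transcriptome responds to 2 days of hypoxia under vehicle. Retnla, a secreted resistin-like molecule induced by IL-4 and IL-13 (chromosome 16, 48842551 to 48844461, plus strand), went from 107 ± 27.9 to 5682 ± 2444 CPM (SD, n = 6), a log2 fold change of 5.74 (SE 0.36). Timp1, an inhibitor of matrix metalloproteinases (chromosome X, 20870166 to 20874735, plus strand), went from 10.8 ± 1.07 to 91.5 ± 25.7 CPM, and the matrix glycoprotein Tnc (chromosome 4, 63959785 to 64047015, minus strand) from 17.0 ± 1.49 to 76.4 ± 6.31 CPM. Cyp1a1, the cytochrome P450 induced by the aryl hydrocarbon receptor (chromosome 9, 57687928 to 57703824, plus strand), fell 29.9-fold, from 30.6 ± 6.45 to 1.02 ± 0.166 CPM (SD, n = 6). By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 6053 of 16935 genes changed, 3208 upward and 2845 downward, and 829 of them by 2-fold or more.

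The other genes with the largest rises were secreted or receptor proteins. Retnlb, the colonic relative of Retnla and its neighbour on chromosome 16 (48816856 to 48818892, plus strand), had 255 counts over the hypoxia group and 2 over the normoxia group, a ratio of 130 (95% counting interval 35.7 to 1081); both normoxia counts were in vehicle replicate 3. Chil4, a chitinase-like protein, had a log2 fold change of 6.05 (SE 1.36), but its hypoxia libraries spread widely (8.86 ± 11.5 CPM, n = 6), its value without hypoxia vehicle replicate 4 was 5.245, and limma-voom did not call it. The neurotensin receptor Ntsr2 rose by 4.68 (SE 0.50), the mucosal scavenger protein Dmbt1 by 4.66 (SE 0.70) and the acute phase protein Orm2 by 4.55 (SE 0.61) on the log2 scale. Chil4 and Orm2 share reads with close relatives, so their single values are uncertain. Among the largest falls were Pla2g2d, a secreted phospholipase A2 of lymphoid tissue (log2 fold change -4.24, SE 0.45), and Ankrd63 (-2.95, SE 0.20). Pck1, the gluconeogenic enzyme, and Plin1, the adipocyte lipid droplet coat, also fell (log2 fold changes -3.15 and -3.03; Pck1 -2.505 without normoxia vehicle replicate 3). The retinoic acid hydroxylase Cyp26b1 fell from 258 ± 352 to 15.9 ± 7.22 CPM (n = 6); its normoxia mean rests on vehicle replicates 1 and 2, and its log2 fold change went from -4.02 to -3.316 without replicate 2. Cyp26b1 and Pck1 were not called by limma-voom.

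Cell cycle genes rose in 29 of 32 tested cases with 0 falls. They included the mitotic kinase Cdk1, from 6.46 ± 1.97 to 26.8 ± 4.80 CPM (n = 6), the kinase Pbk (log2 fold change 2.41) and the spindle protein Nusap1 (1.69). The list was called higher by camera (adjusted p = 3.13e-16), with adjusted p = 0.442 with an estimated correlation. Adjusted over the list alone, 29 rose as well. Erythroid genes rose in 12 of 13 cases, also 12 adjusted over the list alone, among them the band 3 anion exchanger Slc4a1 (3.32) and Trim10 (3.19). Camera gave adjusted p = 2.12e-09 for them, and adjusted p = 0.321 with an estimated correlation. The haemoglobin share given above moved with this group.

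Extracellular matrix genes rose in 17 of 25 cases and 1 fell; adjusted over the list alone, 18 rose and 1 fell. Besides Tnc and Timp1 they included the collagen cross-linking enzymes Loxl2 (log2 fold change 1.63) and Lox (1.37), fibronectin Fn1 (1.32) and the basement membrane collagen Col4a1 (0.87), while osteopontin Spp1 fell (-0.90). The camera adjusted p was 1.45e-08, with adjusted p = 0.442 with an estimated correlation. Of the cholesterol synthesis genes, 14 of 20 rose and 0 fell (16 rose adjusted over the list alone), including Idi1 (1.06), Hsd17b7 (0.85) and the HMG-CoA synthase Hmgcs1 (0.65). This list had a camera adjusted p of 1.92e-05 and adjusted p = 0.516 with an estimated correlation.

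Targets of hypoxia-inducible factor moved unevenly: 11 of 24 rose and 1 fell, with the same counts adjusted over the list alone. Ankrd37 (chromosome 8, 45996902 to 46005707, minus strand) rose 15.8-fold, from 6.69 ± 1.33 to 106 ± 22.1 CPM (n = 6). The mitophagy receptor Bnip3 rose by 1.70 and endothelin Edn1 by 1.63 on the log2 scale, whereas the lipid droplet protein Hilpda fell (-0.54). The angiogenic factor Vegfa was at 804 ± 256 CPM against 905 ± 107 (n = 6; edgeR adjusted p = 0.523). Camera called the list higher (adjusted p = 7.74e-05), with adjusted p = 0.0552 with an estimated correlation. Glycolysis genes rose in 10 of 18 cases and 1 fell, led by lactate dehydrogenase Ldha (1.03), with camera adjusted p = 0.00764 and adjusted p = 0.567 with an estimated correlation. Oxidative phosphorylation genes rose in 11 of 22 cases and 1 fell (camera adjusted p = 0.000235; adjusted p = 0.567 with an estimated correlation). Unfolded protein response genes rose in 10 of 20 cases with 0 falls, among them the chaperone Hspa5 (0.40) and Sdf2l1 (0.82), with camera adjusted p = 0.00501 and adjusted p = 0.567 with an estimated correlation.

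In the list of senescence and its secretory products, 11 of 22 rose and 1 fell, with camera adjusted p = 0.000120 and adjusted p = 0.321 with an estimated correlation. The risers were mostly secreted: the cytokine Il6 (log2 fold change 3.38), the monocyte attractants Ccl2 (3.27) and Ccl7 (2.87), and the neutrophil attractant Cxcl1 (1.63). The growth factor binding protein Igfbp3 fell (-2.55). Of the cell cycle inhibitors that mark senescent cells, Cdkn2b rose (0.53), whereas Cdkn2a (-0.23, edgeR adjusted p = 0.683) and Cdkn1a (0.46, adjusted p = 0.121) did not pass. Cdkn2a was low, at 0.561 ± 0.205 against 0.646 ± 0.368 CPM (n = 6; SE of the log2 fold change 0.40). Its mean stayed under 1 CPM in all 4 groups, so in every comparison a moderate change of Cdkn2a could go uncalled. In acute inflammation, 6 of 17 rose and 0 fell, led by the acute phase protein Saa3 (4.10), with camera adjusted p = 0.0109 and adjusted p = 0.474 with an estimated correlation. Among the targets of ABT-263, Bcl2l1, which encodes BCL-XL, rose from 85.6 ± 6.34 to 115 ± 20.7 CPM (n = 6; edgeR adjusted p = 0.0215), a call lost without hypoxia vehicle replicate 4 (adjusted p = 0.0720). Bcl2l2, which encodes BCL-W and overlaps a gene model on its strand, rose by 0.29 (adjusted p = 0.0114), and Bcl2 stood at 0.18 (adjusted p = 0.0997). The platelet chemokine Pf4 rose by 1.05 on the log2 scale (edgeR adjusted p = 3.9e-06), although the platelet list as a whole was not called (camera adjusted p = 0.365; 3 of 19 rose).

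Several immune, endothelial and epithelial lists were lower in hypoxia. T cell genes fell in 12 of 16 cases, including the coreceptors Cd4 (log2 fold change -0.75) and Cd8a (-1.05), with camera adjusted p = 0.000235 and adjusted p = 0.561 with an estimated correlation. Dendritic cell genes fell in 6 of 12 cases and 1 rose, led by Siglech (-1.67) and Cd209a (-1.30), with camera adjusted p = 0.0109 and adjusted p = 0.442 with an estimated correlation. General capillary genes fell in 5 of 10 cases and 1 rose, led by the fenestral diaphragm protein Plvap (-1.72) and the apelin receptor Aplnr (-1.63), with camera adjusted p = 0.0133 and adjusted p = 0.516 with an estimated correlation. BMP signalling genes fell in 6 of 14 cases, among them the endothelial membrane protein Tmem100 (-0.87), the inhibitory Smad6 (-0.87) and the pulmonary hypertension gene Bmpr2 (-0.36), with camera adjusted p = 0.0335 and adjusted p = 0.516 with an estimated correlation. Aryl hydrocarbon receptor genes fell in 4 of 6 cases (camera adjusted p = 0.0479; adjusted p = 0.474 with an estimated correlation). Ciliated cell genes fell in 6 of 12 cases and 1 rose (0.0336; adjusted p = 0.567 with an estimated correlation), adipose genes fell in 5 of 8 (0.0479; adjusted p = 0.567 with an estimated correlation) and B cell genes in 3 of 19 (0.0479; adjusted p = 0.782 with an estimated correlation). Over all genes 2845 of 16935 fell and 3208 rose. The 3 of 19 B cell genes are near that share, and the exact permutation did not call the B cell list. In all, camera called 18 of 45 lists, 10 higher and 8 lower. With an estimated correlation 0 of them held, against 25 lists called with fry and 24 with the exact permutation of list scores.

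The second comparison asked what ABT-263 does to the lung in normoxia. Some genes of platelets and of the circadian clock changed, although with an estimated correlation camera called 0 lists in this comparison. Gp1bb, a subunit of the platelet receptor for von Willebrand factor (chromosome 16, 18620317 to 18622403, minus strand), rose from 1.91 ± 0.845 to 7.04 ± 2.30 CPM (SD, n = 6; log2 fold change 1.87, SE 0.28), and Gp9, its partner in the same receptor (chromosome 6, 87778072 to 87779768, plus strand), from 7.17 ± 1.14 to 17.1 ± 5.24 CPM. The clock output factor Dbp (chromosome 7, 45705088 to 45710203, plus strand) rose from 20.6 ± 6.62 to 58.6 ± 23.6 CPM. The core clock activator Arntl, known as BMAL1 (chromosome 7, 113207465 to 113314126, plus strand), fell from 25.2 ± 3.42 to 14.7 ± 3.25 CPM. The clock genes Tef (0.77) and Nr1d1 (0.70), and Mfsd2b, a sphingosine-1-phosphate exporter of red cells and platelets (0.62), rose as well on the log2 scale.

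Those 7 genes were the only ones the edgeR quasi-likelihood test called, 6 higher and 1 lower, with Benjamini-Hochberg adjusted p between 0.0109 for Gp1bb and 0.0411 for Tef, Nr1d1 and Mfsd2b. An unadjusted p under 0.05 was found for 1154 genes, where chance gives 847 on average. With 1 library left out that number ran from 710 (normoxia vehicle replicate 1) to 1451 (hypoxia ABT-263 replicate 1). Genes vary together within groups, so the excess is not evidence of a wider drug effect. DESeq2 called 30 genes and limma-voom 6, whereas a fit of only the 2 groups compared, and a fit without the 3 libraries that stood apart, called 0. The count also fell to 4 without normoxia vehicle replicate 1 or 3, normoxia ABT-263 replicate 3 or hypoxia vehicle replicate 3, to 3 without normoxia vehicle replicate 2, to 2 without normoxia ABT-263 replicate 1 and to 1 without normoxia vehicle replicate 4 or normoxia ABT-263 replicate 4, and it was 13 without normoxia ABT-263 replicate 2. Gp1bb was called in all 24 runs that left out 1 library. Gp9 lost its call without normoxia vehicle replicate 4 or normoxia ABT-263 replicate 4, Dbp without those or normoxia ABT-263 replicate 1, and Arntl without any of those or normoxia vehicle replicate 2, with adjusted p up to 0.0568 in each case. Nr1d1 lost its call in 17 of the runs and Tef and Mfsd2b in 12 each, with adjusted p up to 0.2002 for all 3 without normoxia vehicle replicate 2, while Pf4 passed without hypoxia vehicle replicate 2 (0.0476) or 4 (0.0313) and Scd1 without normoxia vehicle replicate 6 (0.0254). Gp1bb shares its strand with an overlapping gene, Sept5, and Dbp, Nr1d1, Tef and Arntl overlap genes on the opposite strand, so reads of those neighbours could enter their values.

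**Figure D2:**
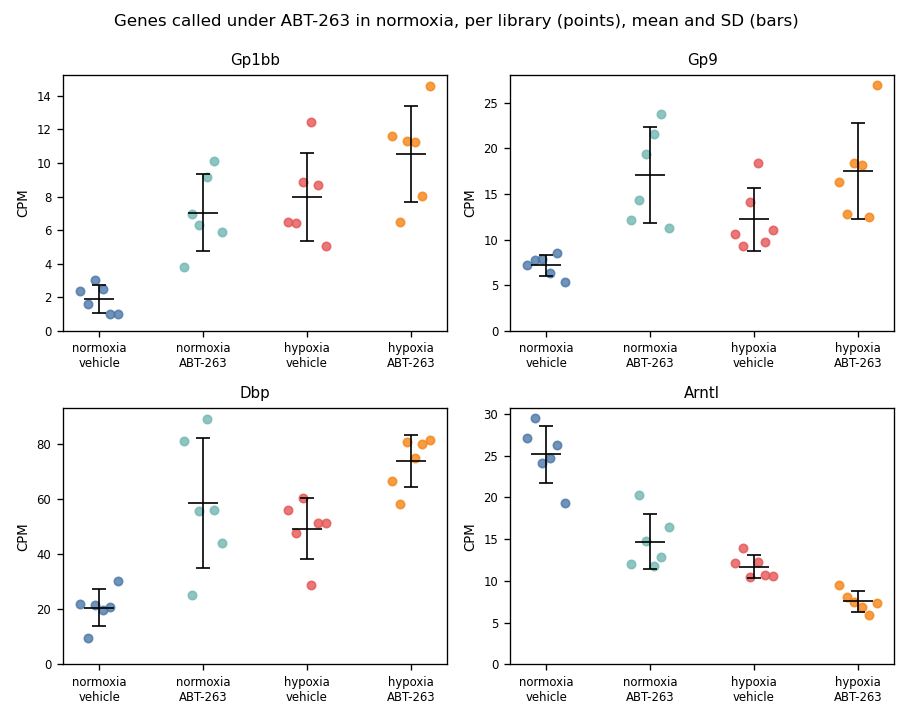
TMM-scaled CPM of Gp1bb, Gp9, Dbp and Arntl in each library (points) of the 4 groups, with mean and SD (bars). In normoxia the ABT-263 libraries average 7.04 against 1.91 CPM for Gp1bb, 17.1 against 7.17 for Gp9, 58.6 against 20.6 for Dbp and 14.7 against 25.2 for Arntl.

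Across the platelet and megakaryocyte list, 18 of 19 genes had a positive fold change under ABT-263, with a median of 0.72. Over all genes 2 of 19 rose; adjusted over the list alone 17 rose and 1 fell. Integrin Itga2b stood at 0.96, Treml1 at 1.21 and Pf4 at 0.67 on the log2 scale (edgeR adjusted p for Pf4 = 0.104). Camera called the list higher (adjusted p = 1.02e-22), with adjusted p = 0.0809 with an estimated correlation, and its score was higher in all 6 drug libraries than in any vehicle library (exact permutation p = 0.00216, adjusted 0.0487). Clock genes rose in 3 of 18 cases and 1 fell, and adjusted over the list alone 9 rose and 4 fell, with camera adjusted p = 3.13e-05 and adjusted p = 0.126 with an estimated correlation.

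Lipid synthesis and B cell lists were called lower by camera. With all 24 libraries and the filter on low counts the edgeR quasi-likelihood test called none of their genes over all genes. Scd1 passed without that filter, with the residual component as covariate or without normoxia vehicle replicate 6 (adjusted p = 0.0254), and DESeq2 called Scd1 and Bank1. Cholesterol synthesis had 20 of 20 negative fold changes and a median of -0.26, and 8 genes fell adjusted over the list alone; Hmgcs1 was at -0.40 (edgeR adjusted p = 0.231) and the sterol carrier Stard4 at -0.41. The camera adjusted p was 7.26e-15, with adjusted p = 0.126 with an estimated correlation. Fatty acid synthesis had a median of -0.33 and 6 falls adjusted over the list alone. Its desaturase Scd1 stood at 1142 against 1892 CPM (log2 fold change -0.73, edgeR adjusted p = 0.0883), the synthase Fasn at -0.35 and the elongase Elovl1 at -0.42. The list's camera adjusted p was 8.75e-10, with adjusted p = 0.105 with an estimated correlation, and the exact permutation of its score passed (adjusted 0.0487). B cell genes had a median of -0.49, and 10 of 19 fell adjusted over the list alone, with Fcmr at -0.84, Bank1 at -0.76 and the antigen receptor component Cd79a at -0.74. For them camera gave adjusted p = 2.24e-14, with adjusted p = 0.185 with an estimated correlation.

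Other lists that camera called in normoxia lost the call with an estimated correlation. Cell cycle was called higher (median 0.41, Birc5 0.65, Cenpf 0.71, Cdk1 0.61; camera adjusted p = 1.09e-10, adjusted p = 0.529 with an estimated correlation) with 0 genes passing in the list alone. Erythroid cells were higher with 4 rises adjusted over the list alone (2.93e-06; adjusted p = 0.405 with an estimated correlation). Matrix was called lower (median -0.17; 5.72e-06; adjusted p = 0.529 with an estimated correlation), as were general capillary, pan-endothelial, T cell and both alveolar epithelial lists (adjusted p = 0.265, 0.529, 0.720, 0.529 and 0.606 with an estimated correlation). Cardiac muscle, glucocorticoid response, oxidative phosphorylation and club cells were called higher (adjusted p = 0.590, 0.529, 0.720 and 0.606 with an estimated correlation). Normoxia vehicle replicate 2 had a low cardiac muscle score (2.32 against a median of 5.94 in the others), and without the 3 libraries that stood apart, this 1 among them, the calls of cardiac muscle (0.133), oxidative phosphorylation (0.122), club cells (0.0905) and alveolar type 1 cells (0.0681) were lost. NK cells were not called: the camera direction was down, but the median (0.40) and mean (0.48) fold changes were positive and the mean log2 CPM differed by -0.11. The senescence list was not called either (camera adjusted p = 0.983, direction down, median 0.08), and the drug's targets Bcl2 (-0.11), Bcl2l1 (0.21) and Bcl2l2 (-0.16) and the markers Cdkn2a (0.37), Cdkn1a (0.27) and Vegfa (0.01) did not pass. At 0.857 against 0.646 CPM, Cdkn2a was too low for a moderate change to be seen reliably.

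The third comparison asked what ABT-263 does in hypoxic lung. B cell genes were lower together. All 19 had a negative fold change, with a median of -0.74: the IgD heavy chain Ighd (chromosome 12, 113406604 to 113416324, minus strand) was at 32.6 ± 9.39 against 64.8 ± 9.33 CPM (SD, n = 6), the follicular homing receptor Cxcr5 at 4.55 ± 1.46 against 8.50 ± 1.78 CPM, and Cd79a at 15.7 ± 4.79 against 26.7 ± 6.83 CPM. Adjusted over the list alone 18 of 19 fell, and over all genes 0 did. The list was called by camera (adjusted p = 4.78e-41), with adjusted p = 0.0148 with an estimated correlation, and by fry (0.0256). The call with an estimated correlation was lost without hypoxia vehicle replicate 6 (0.0600) or hypoxia ABT-263 replicate 2 (0.0840). Its score was lower in all 6 drug libraries than in any vehicle library (exact permutation p = 0.00216, adjusted 0.0974).

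No single gene passed in hypoxia: the edgeR quasi-likelihood test called 0 of 16935, with 543 at an unadjusted p under 0.05, DESeq2 called 4 (Ighd, Plk2 and Cxcr5 lower, Pi16 higher) and limma-voom 0. The smallest p were those of Ighd (log2 fold change -0.99), the kinase Plk2 (-0.73) and the fibroblast protein Pi16 (0.70), each with an edgeR adjusted p of 0.226. Without hypoxia vehicle replicate 6 edgeR called 1 gene, Plk2 (adjusted p = 0.0106). Simulated 2-fold changes were called in 88.1% of cases in this comparison. The simulated genes varied independently, however, and the real test gave 543 unadjusted p under 0.05 where chance gives 847. The share called may therefore be too high for the real libraries. None of the fixed genes passed, with Bcl2 at -0.03, Bcl2l1 at -0.01, Bcl2l2 at -0.14, Cdkn2a at -0.20, Cdkn1a at -0.27, Vegfa at -0.17 and Pf4 at 0.34 on the log2 scale. Cdkn2a was again low, at 0.486 against 0.561 CPM, where a moderate change is hard to see. The senescence list was not called (camera adjusted p = 0.229, direction down, median 0.01, mean -0.07), although it passed without the 3 libraries that stood apart (0.0490).

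Lymphatic endothelial genes were higher, with 5 of 5 positive fold changes, a median of 0.39 and 2 rises adjusted over the list alone, 1 of them Mmrn1, which platelets express too (0.55). This was the other list that held (camera adjusted p = 2.68e-05; adjusted p = 0.0431 with an estimated correlation), though fry did not call it (0.0642). Its call with an estimated correlation was lost, with adjusted p up to 0.221, without normoxia vehicle replicates 2 to 6, normoxia ABT-263 replicates 1, 3 or 6, hypoxia vehicle replicates 3, 4 or 6 or hypoxia ABT-263 replicates 1, 2, 4, 5 or 6. Platelet genes again had positive fold changes, 19 of 19, with a median of 0.34, Itga2b at 0.54 and Gp9 at 0.52 (camera adjusted p = 4.34e-09; adjusted p = 0.294 with an estimated correlation). NK cell genes were called lower (median -0.66, Klra8 -0.96, Klre1 -0.80; camera adjusted p = 1.26e-09; adjusted p = 0.294 with an estimated correlation), as were T cell genes (median -0.23, Il7r -0.46, Cd2 -0.48, Lat -0.25; 5.47e-07; adjusted p = 0.378 with an estimated correlation). Fibroblast genes were called higher (median 0.24, Lum 0.75, Mfap5 0.38; 8.64e-07; adjusted p = 0.294 with an estimated correlation), as were neutrophil genes (median 0.40, S100a8 0.59; 1.69e-06; adjusted p = 0.203 with an estimated correlation). The hypoxia-inducible factor targets were called lower with a median of -0.06 (0.00878; adjusted p = 0.214 with an estimated correlation). The remaining calls were erythroid, heat shock, smooth muscle, monocyte, adipose, interferon, vascular tone and oxidative stress lists higher and immediate early and alveolar type 1 lists lower, all lost with an estimated correlation (adjusted p = 0.294 for smooth muscle and 0.503 to 0.717 for the others).

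**Figure D3:**
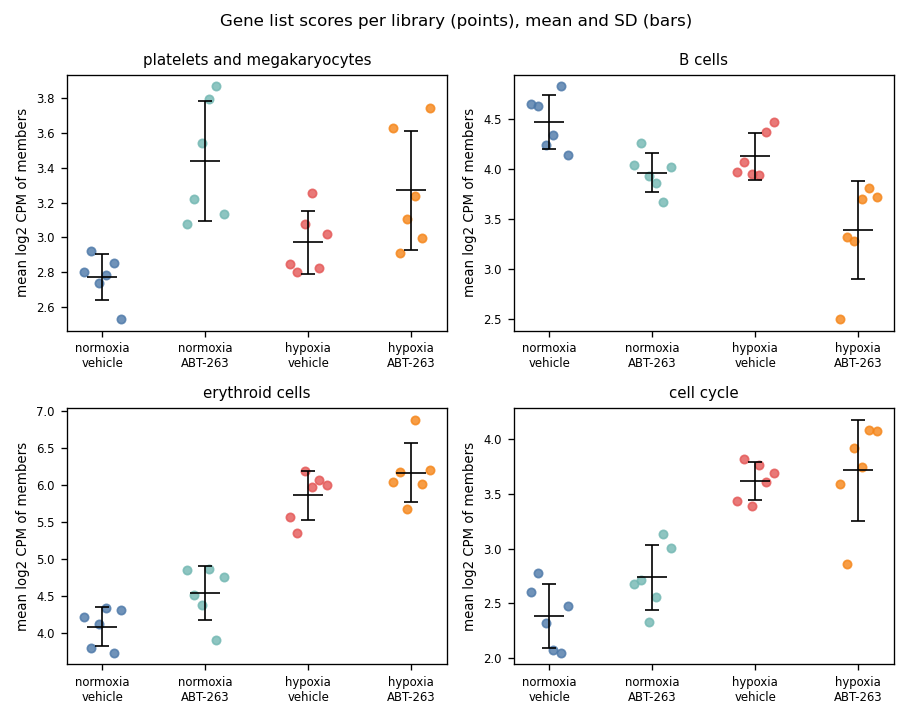
Mean log2 CPM of the tested members of 4 gene lists in each library (points) of the 4 groups, with mean and SD (bars). Under ABT-263 the platelet score differs by 0.67 in normoxia and the B cell score by -0.74 in hypoxia; under hypoxia with vehicle the erythroid score differs by 1.78 and the cell cycle score by 1.23.

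The fourth comparison asked how the lung responds to hypoxia under ABT-263. Matrix genes rose in 22 of 25 cases and 1 fell, with Timp1 at 100.2 ± 19.0 against 10.8 ± 2.99 CPM and Tnc at 55.9 ± 7.08 against 13.8 ± 2.61 CPM (SD, n = 6). Cell cycle genes rose in 27 of 32 cases, including the spindle protein Nusap1 (log2 fold change 1.49). Retnlb had 231 counts in hypoxia and 0 in normoxia, at least 76.2-fold higher against the floor of 3 counts over the group. Dmbt1, with 2 normoxia counts, had a ratio of 103 (95% counting interval 28.1 to 855), and the opioid precursor Pdyn, with 1, in normoxia ABT-263 replicate 1, a ratio of 109 (19.1 to 4338). The interval does not cover the spread of Dmbt1 between libraries: hypoxia ABT-263 replicate 6 was at 7.46 CPM against a median of 1.35 in the others, and without it the fitted log2 fold change was 5.522. Cyp1a1 fell by 3.20, Pla2g2d by 3.07 and Orm3 by 3.42 on the log2 scale; Cyp1a1 in the hypoxia group rests partly on ABT-263 replicate 4 (7.84 CPM against a median of 0.845 in the others; log2 fold change -4.048 without it).

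By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 6948 genes changed under ABT-263, 3656 upward and 3292 downward. Of these, 2697 rose and 2028 fell in both hypoxia comparisons, where independent lists would share 693 and 553, and 0 called genes moved in opposite directions. The fold changes correlated across genes, which are not independent replicates, with r = 0.846 (Spearman's rho 0.840). Camera called 18 lists, 13 higher and 5 lower, and 0 held with an estimated correlation. They included matrix (camera adjusted p = 7.39e-13; adjusted p = 0.405 with an estimated correlation), cell cycle (2.85e-11; adjusted p = 0.423 with an estimated correlation), cholesterol synthesis with 18 of 20 risers (7.66e-10; adjusted p = 0.405 with an estimated correlation), T cells with 14 of 16 falling (3.82e-05; adjusted p = 0.531 with an estimated correlation) and B cells with 10 of 19 falling (0.00107; adjusted p = 0.634 with an estimated correlation). NK cell genes fell in 12 of 13 cases (0.0105; adjusted p = 0.634 with an estimated correlation), a call lost without the 3 libraries that stood apart (0.196). Bcl2 (0.26) and Bcl2l2 (0.32) rose, as did Pf4 (0.71), while Bcl2l1 (0.21, edgeR adjusted p = 0.239), Cdkn2a (-0.81, 0.110), Cdkn1a (-0.08, 0.816) and Vegfa (-0.35, 0.159) did not pass. Without normoxia ABT-263 replicate 4, Bcl2l1 passed (adjusted p = 0.0339).

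**Figure D4:**
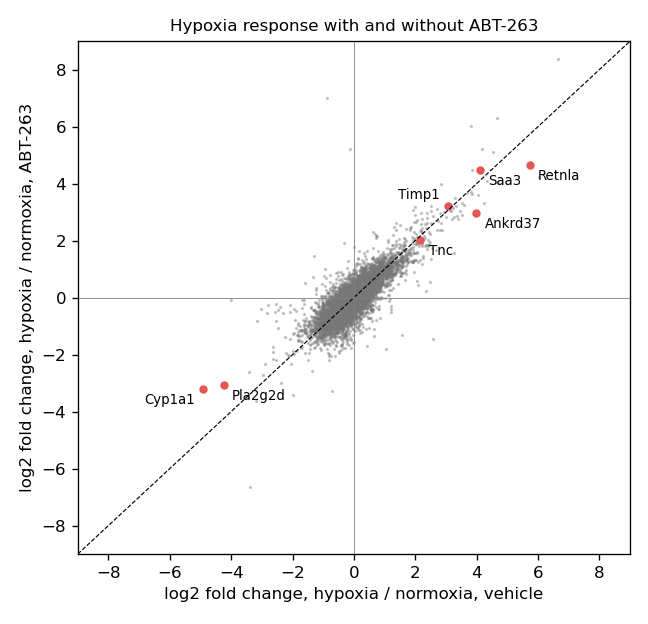
Log2 fold changes of hypoxia against normoxia for 16935 genes, under vehicle (x axis) and under ABT-263 (y axis); each grey point is a gene, the dashed line marks equal change, and named genes are in red. The points follow the line (r = 0.846), with Retnla, Saa3, Timp1, Tnc and Ankrd37 raised and Cyp1a1 and Pla2g2d lowered in both.

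The last comparison asked whether ABT-263 alters the response to hypoxia. Single genes gave no such difference: the edgeR quasi-likelihood test called 0 of 16935, with 625 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. The smallest p were those of Shisa2, a WNT and FGF receptor regulator (interaction 1.17 on the log2 scale), the stromelysin Mmp3 (0.81) and the serotonin receptor Htr2a (1.14), each with an edgeR adjusted p of 0.991. Fatty acid synthesis had a positive interaction in 14 of 14 genes, with a median of 0.32, Fasn at 0.44 and Elovl1 at 0.60 (camera adjusted p = 1.62e-07; adjusted p = 0.395 with an estimated correlation), and 2 genes passed adjusted over the list alone. Cholesterol synthesis had one in 20 of 20 genes, with a median of 0.26, Insig1 at 0.36 and Hsd17b7 at 0.35 (4.86e-07; adjusted p = 0.452 with an estimated correlation). The fixed genes gave 0.08 for Bcl2, -0.22 for Bcl2l1, 0.03 for Bcl2l2, -0.58 for Cdkn2a, -0.54 for Cdkn1a, -0.34 for Pf4 and -0.18 for Vegfa. Camera called 18 lists, and 0 held with an estimated correlation or with fry; for cardiac muscle the median (-0.14) and the mean (0.05) had opposite signs. Simulated 2-fold interactions were called in 52.2% of cases, so real ones of that size can go uncalled. The drug's fold changes in normoxia and in hypoxia, from separate libraries, correlated across genes with r = 0.0527, and 50.2% had the same sign. Over the 7 genes called in normoxia r was 0.910 (slope 0.435). Those genes were chosen by their normoxia values, and Arntl alone among them falls, which weighs heavily in r. This r therefore does not test whether the drug's effect recurs in hypoxia.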

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

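All the tests of explanations in this part were chosen after the patterns had been seen, apart from the 2 that use the mitochondrial share, and the thresholds for single libraries and for differing lists were set before the data were examined.

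The mean score of the platelet genes was higher by 0.67 under ABT-263 in normoxia, and Gp1bb and Gp9 were called singly. With an estimated correlation camera called 0 lists in this comparison, so the call of the platelet list did not hold. A difference in the mitochondrial share between libraries is argued against, since with that share as covariate the mean fold change of the list was 0.842 (SE 0.125) against 0.669 without it. More blood in the samples stays open, because its signs divide. The neutrophil and T cell score, which tissue cells also set, differed by -0.0783 and the platelet score minus it by 0.747 (exact permutation p = 0.00216). Normoxia ABT-263 replicate 5 raised the drug group's neutrophil and T cell score. It stood at 3.56 for T cells (median of the others 2.54) and 3.19 for neutrophils (2.41). On the other side, the haemoglobin share was 0.600% against 0.385% (adjusted exact permutation p = 0.277), and erythroid genes were called higher by camera (adjusted p = 0.405 with an estimated correlation). The platelet score minus the log2 haemoglobin share differed by 0.09996 (exact permutation p = 0.827). The erythroid list contains haemoglobin genes, so these values are not separate signs. An effect of the drug on platelets may be the reason too, and these data do not decide.

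Some clock genes shifted under ABT-263 in normoxia. The clock list lost its camera call with an estimated correlation, which left 0 lists called in this comparison. Nr1d1 lost its single call in 17 of 24 runs without 1 library, and Tef in 12. With all libraries, Arntl was called lower and Dbp, Tef and Nr1d1 higher. A difference in the time of day at which groups were collected could do this: without the genes called singly, genes in antiphase to Arntl lay 0.903 above genes in phase with it on the log2 scale, and in hypoxia, with all 17 genes kept, the difference was 0.612, the shape of a phase shift. A drug effect at both oxygen levels is possible too. The fold changes of 18 clock genes in normoxia and hypoxia, from separate libraries, correlated with r = 0.843. This r cannot separate the explanations, because genes in phase with Arntl and genes in antiphase shift as sets. A difference in collection time at both oxygen levels would also give a high r. The 18 genes also include Arntl, Dbp, Tef and Nr1d1, which were called in normoxia. Collection times are not in the labels, and both explanations stay open for the drug. Under vehicle, Arntl was also lower in hypoxia than in normoxia (11.7 against 25.2 CPM). Dbp (49.4 against 20.6 CPM) and Tef (202 against 146 CPM) were higher there, while Nr1d1 was about level (60.1 against 62.5 CPM). A difference in collection time could therefore bear on the hypoxia comparisons as well.

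B cell genes were lower under ABT-263 in hypoxia, in all 6 libraries against all 6. A few libraries that stand apart remain open as part of it: the list kept an adjusted p of 0.0293 with an estimated correlation without 3 of them, of which 1 is in this comparison, but the highest over 24 runs without 1 library was 0.0840 (0.0600 without hypoxia vehicle replicate 6), and the mean difference was -0.492 (SE 0.136) without that library and hypoxia ABT-263 replicate 1, against -0.738. An equal loss of all lymphocytes is argued against by the B cell minus T cell score, which differed by -0.457 (exact permutation p = 0.00216) and by -0.306 in normoxia. The normoxia value rests partly on ABT-263 replicate 5, whose T cell score was 3.56 against a median of 2.54 in the others. The mitochondrial share as covariate left the mean fold change at -0.702 (SE 0.181). Loss of B cells to inhibition of BCL-2 family proteins may be the reason, as a hypothesis found and examined on the same libraries, and since NK cell genes were lower by a similar amount (median -0.66 against -0.74), a loss shared by both stays open.

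Other splits of the same libraries gave the number of genes called when libraries are divided without regard to treatment, with 100 splits each, the real one included; splits over all 24 libraries were added after those over the 12 libraries compared had been seen. For hypoxia under vehicle the real split was the only 1 as large. It called 6053 genes against a highest other of 2548 in the fit of 24 libraries, and 6091 against 800 in the fit of 12. A chance division of the libraries is therefore unlikely to give such a count under vehicle. With 100 splits the share cannot go below 1 in 100, and a batch that followed the groups would not show. For hypoxia under ABT-263 the real split was again the only 1, with 6948 against 5801 and 6052 against 4359. For ABT-263 in normoxia the 7 genes of the fit with 24 libraries were matched by 1 split, the real one (highest other 1). With 12 libraries, the splits seen first, none of the 7 was called: the real count was 0, which all 100 splits reach by definition, and another split called 10. The splits of 12 libraries therefore cannot test the 7 genes. Those of 24 set the real split above the others, but the calls depend on the fit, and chance is not excluded. For ABT-263 in hypoxia the real count was 0 in both fits, again reached by all 100 splits by definition, and the highest others were 5821 and 5285, which points to a structure of the samples within groups. That split had the largest difference of the first residual component, 2.21, and the highest other splits of the hypoxia comparisons ranked 40 (2548 genes) and 2 (800) under vehicle and 9 (5801 and 4359) under ABT-263 on it. For the interaction, tested with limma on permuted residuals, the real count of 0 was likewise reached by all 100 splits, with a highest other of 2123.

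Of 355 groups of 6 libraries tested for a single library far from the others, 27 had one, where about 1 in 20 or 18 would by chance. In normoxia ABT-263 replicate 5, the mean log2 CPM was 4.96 for NK cells (median of the others 2.09), 3.56 for T cells (2.54), 3.19 for neutrophils (2.41), 5.30 for monocytes and interstitial macrophages (4.12) and 5.65 for interferon response (4.03). In hypoxia ABT-263 replicate 1, NK cells were at 0.846 (1.90), BMP signalling at 6.03 (5.79), alveolar type 1 cells at 8.46 (8.07), Ighd at 13.8 CPM (37.1), Cdkn1a at 104 CPM (48.1) and Bcl2l1 at 157 CPM (108). Normoxia vehicle replicate 2 had cardiac muscle genes at 2.32 against 5.94 in the median of the others. Hypoxia vehicle replicate 6 had Cd79a at 40.1 CPM (24.1), Cd2 at 23.2 (15.7), Cyp26b1 at 30.2 (12.8) and Lum at 4.03 (2.93). Single values elsewhere were Lum at 2.36 CPM in hypoxia ABT-263 replicate 3 (5.70), Dmbt1 at 5.72 in hypoxia vehicle replicate 3 (1.77) and 7.46 in hypoxia ABT-263 replicate 6 (1.35), Orm2 at 5.98 in hypoxia vehicle replicate 2 (2.02) and Cyp1a1 at 7.84 in hypoxia ABT-263 replicate 4 (0.845). Further ones were Pla2g2d at 3.50 CPM in normoxia ABT-263 replicate 4 (1.92), Bcl2 at 25.4 in hypoxia vehicle replicate 5 (19.99), Retnlb at 0.129 in normoxia vehicle replicate 3 and Pdyn at 0.0664 in normoxia ABT-263 replicate 1 (both 0 in the others). Alveolar type 2 cells were at 8.96 in normoxia ABT-263 replicate 3 (9.34) and immediate early genes at 5.52 in hypoxia vehicle replicate 4 (4.99).

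The response to hypoxia differed between ABT-263 and vehicle for 18 lists by camera on the interaction, and for 0 of them with an estimated correlation or with fry. Median interactions were positive for adipose tissue (2.06), general capillary endothelium (0.39), neutrophils (0.37), fibroblasts (0.37), lymphatic endothelium (0.35), fatty acid synthesis (0.32), alveolar type 2 cells (0.30), extracellular matrix (0.30), cholesterol synthesis (0.26), monocytes and interstitial macrophages (0.19) and pan-endothelium (0.18). They were negative for NK cells (-1.12), platelets and megakaryocytes (-0.34), circadian clock (-0.33), B cells (-0.20), cell cycle (-0.19), cardiac muscle (-0.14) and hypoxia-inducible factor targets (-0.13). Without the 3 libraries that stood apart, NK cells and cardiac muscle turned direction and lost the call (adjusted p = 0.694 and 0.608), and pan-endothelium (0.348) and lymphatic endothelium (0.0669) lost it.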

How the results depend on the processing

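The fit without 3 libraries, the residual component as covariate, the exact permutation of list scores and the runs of 2 lists without 1 library were chosen after seeing the data; the other alternatives were planned. The counts of genes changed by hypoxia, under vehicle and under ABT-263, stayed within 1.5 times their values under every alternative, from 5104 (no filter) to 8398 (residual component) and from 5940 (no filter) to 8867 (residual component). The residual component averages 0 in every group, so as covariate it takes out spread within groups and cannot correct a difference between them. More calls with it are therefore not added evidence of change. With it, 46.3% of the genes changed by hypoxia under vehicle were higher, against 52.9985% without it. Under ABT-263 the shares were 49.4% and 52.6%. The interaction count was 0 under every alternative. For ABT-263 in normoxia the 7 genes became 0 in a fit of only the groups compared, 30 with DESeq2, 0 without the 3 libraries and 81 with the residual component as covariate, and 1 to 13 with each library left out in turn. For ABT-263 in hypoxia the 0 genes became 4 with DESeq2, and 0 to 1 with each library left out. The numbers of lists called, 18 for hypoxia under vehicle, 17 for ABT-263 in normoxia and 18 in each other comparison, became 0, 0, 2, 0 and 0 with an estimated correlation (hypoxia under vehicle, ABT-263 in normoxia, ABT-263 in hypoxia, hypoxia under ABT-263, interaction). With fry they became, in the same order, 25, 4, 1, 26 and 0, with the exact permutation of scores 24, 2, 0 and 22 (not run for the interaction), and without the 3 libraries 19, 20, 25, 14 and 17. The cause was not tested for any of these.

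Reversals were tabulated for the named genes and the called lists. Vegfa under ABT-263 in normoxia was at -0.02142 with limma-voom and -0.02415 with the residual component, and -0.0610 to 0.0919 with each library left out. Without the 3 libraries Bcl2 under ABT-263 in hypoxia was at 0.00597 and the interaction of Bcl2l2 at -0.02118. With each library left out, Bcl2 under ABT-263 in hypoxia ran from -0.0654 to 0.0289, Bcl2l1 there from -0.115 to 0.0846, the interaction of Bcl2l2 from -0.0370 to 0.0837 and Cdkn1a in hypoxia under ABT-263 from -0.305 to 0.106. The interaction lists NK cells and cardiac muscle turned direction without the 3 libraries, with adjusted p = 0.694 and 0.608. No paired analysis was possible because the replicate numbers were given in accession order and pair nothing.

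Depth limits the genes under 3 counts per group, where only bounds or counting intervals can be given.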

Other observations

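The gene families in this part were chosen after seeing the data. Each was tested by an exact permutation of its mean log2 CPM, adjusted over 40 tests (10 families in 4 comparisons). The adjustment does not cover that choice, so the p-values describe the families and are not independent evidence.

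Several families changed in hypoxia under vehicle; the chemokine, acute phase and type 2 families share genes such as Ccl2, Lcn2 and Ccl17 with the lists. Proteasome subunits, which degrade ubiquitinated proteins, rose in 26 of 37 cases with 0 falls and a median log2 fold change of 0.40 (exact permutation p = 0.00216, adjusted 0.00787), led by the deubiquitinase Psmd14 (1.05); under ABT-263 hypoxia also raised 26. Genes of polyamine synthesis and its control rose in 7 of 8 cases (adjusted 0.00787), with Amd1, the decarboxylase that supplies aminopropyl groups, at 135 against 28.1 CPM (2.27) and ornithine decarboxylase Odc1 at 173 against 108 CPM (0.67). Molecules of type 2 immunity rose in 10 of 11 cases (adjusted 0.00787): besides the resistin-like and chitinase-like genes, arginase Arg1 (1.24), the mucin Muc5ac (1.39) and the chemokine Ccl17 (0.97) rose, and Alox15 (-1.23, edgeR adjusted p = 0.151) did not pass. Acute phase proteins rose in 8 of 12 cases and 1 fell, with Orm1 at 17.9 against 1.26 CPM and lipocalin Lcn2 at 254 against 65.2 CPM; Orm3 fell (-1.99), and the Orm genes share reads.

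Tubulins rose in 8 of 15 cases and 2 fell, with Tubb3 at 4.59 against 0.270 CPM, Tubg2 at -0.78 and Tubb4a at -0.71. Chemokines rose in 12 of 28 cases and 1 fell, and cytosolic ribosomal proteins rose in 50 of 83 cases with 0 falls (exact permutation p = 0.0130, adjusted 0.0346); under ABT-263 32 ribosomal genes rose and the family did not pass (adjusted 0.132). Voltage-gated potassium channels, whose closing contracts pulmonary artery muscle, fell in 7 of 17 cases and 1 rose (adjusted 0.00787; under ABT-263 4 fell and 1 rose, adjusted 0.0487), among them Kcna2 (-0.89) and Kcnq5 (-1.04). Histone genes fell in 7 of 18 cases and 2 rose (adjusted 0.0124; under ABT-263 the family did not pass, adjusted 0.0764), and since the libraries were made from mRNA, histone messages without a poly(A) tail are poorly covered. MHC class II, the remaining family, passed in neither hypoxia comparison. Of its 11 genes 1 rose and 1 fell under vehicle (exact permutation adjusted p = 0.286), and 3 fell under ABT-263 (adjusted 0.376). Under ABT-263 against vehicle no gene of these 10 families was called at either oxygen level (edgeR quasi-likelihood test). Over all genes only 7 of 16935 were called in normoxia and 0 in hypoxia, so this says little about the families.

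Within groups the libraries varied along 1 main direction. The first principal component of the residuals from the group means held 26.6% of the residual variance and correlated over the 24 libraries with the mitochondrial share (Pearson's r = 0.842, Spearman's rho = 0.874, permutation p = 1e-05 for each, the smallest that 100000 permutations can give; r = 0.836 without the 2 libraries farthest from the median). No other property of the libraries was tested against it. Hypoxia vehicle replicate 5, with the highest score (1.82), had 24411 detected genes, a TMM factor of 1.08 and a Scgb1a1 share of 4.98%. Hypoxia vehicle replicate 3, with the lowest (-1.44), had 22863, 0.927 and 8.29%. The component may therefore follow library composition more broadly than the mitochondrial share.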
